A study of Mus musculus with 32 samples.

How the data were processed

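Polyadenylated RNA was measured in 32 libraries of mouse PSM cells grown from epiblast stem cells with a Hes7 luciferase reporter, 16 from the time course Ex4 and 16 from Ex5. Per the labels' protocols, total RNA (200 ng) was turned into libraries with a strand-specific mRNA kit, each dish was frozen at its own time, and 1 further dish was followed in a luminometer, whose record was not analysed here. The deposited table holds raw read counts per gene symbol, which per the submitters' processing notes involved bcl2fastq 2.17.1.14, cutadapt 1.14, HISAT2 2.1.0 and HTSeq 0.6.1 with the genome build mm10. The gene annotation and the strand setting of the counting are not given in the sources used here, so reads of overlapping genes may be shared. Columns were assigned to samples through the sample descriptions, which match them 1 to 1, and the number of columns left unused was 0. The table has 21886 genes, of which 3706 are 0 in all libraries, and no 2 libraries were identical (0 identical pairs). Gene positions come from GENCODE M21 on GRCm38, the assembly behind mm10, matched by symbol; 99.8% of tested genes had a GC content and length there.

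Scaled counts (CPM) were computed with TMM factors (edgeR 4.0.16 in R 4.3.3), and the 11772 genes with at least 1 CPM in at least 16 libraries were tested. The clock phase came from Hes7: its log2 CPM (prior count 0.5) was fitted by least squares with a level, slope, amplitude and peak time per experiment and 1 common period, searched from 90 to 240 min in steps of 1 min, with a 95% profile interval. All genes were then fitted with edgeR's quasi-likelihood model with an intercept and a linear slope per experiment, centred at 285 min, and shared cosine and sine terms of the phase. Rhythm was tested on both terms together, trend on the mean of the 2 slopes, level and slope on the difference Ex5 minus Ex4, and rhythm differences on the interaction with experiment, each with Benjamini-Hochberg adjustment at 0.05. Standard errors of amplitudes and phases derive from the F statistic and leave out the error of the period and of the Hes7 phase. Slopes are log2 changes per 100 min. Depth was 16.1 to 29.5 M counts per library, and each time point has 1 library per experiment, so the spread was estimated from the deviations from the fitted curves.

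The 20 gene lists, the design and the alternatives were fixed before the data were examined. The lists are Notch pathway and Hes/Hey, FGF/ERK, Wnt, PSM, anterior PSM and somite, pluripotency and epiblast, neural, endoderm, lateral, intermediate and vascular mesoderm, Hox, G1/S, G2/M, circadian clock, immediate early, glycolysis, stress and amino acid response, BMP, retinoic acid, YAP and cholesterol synthesis. Lists were tested for rhythm with Fisher's exact test and for trend and level with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation; fry was run beside them. Named genes followed a fixed rule. For rhythm these were Hes7, the 20 genes with the largest fold among those past the test with a mean of at least 5 CPM and phases within 1/6 of a cycle between the experiments, up to 5 members of each list past the test, and the Notch, FGF and Wnt list members. For trend these were the 10 rising and 10 falling genes with the largest slopes at 5 CPM or more and the same sign in both experiments, and up to 4 members per list. For level these were the 5 highest and 5 lowest, and for slope differences the 5 smallest p-values. Predicted gene models were left out (3 among the rhythmic genes otherwise eligible). The luciferase row was seen only in the table and was added.

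The procedure was tested on simulated counts for the 11772 genes with 200 genes changed per comparison. Counts were drawn for each gene independently, around a mean that was flat but for the tested change. Trends, level differences and deviations shared by the genes of a library were not simulated, so the shares below hold for that simpler setting. For rhythm, 68.7% of genes cycling 1.2-fold, 97.0% at 1.5-fold and 100% at 2-fold were recovered, with a median phase error of 3.00, 1.41 and 0.724 min, and 6.35% of the calls were false. For trend, 80.6% were recovered at 0.1 log2 per 100 min and 100% at 0.3. For slope differences, 13.4% were recovered at 0.1 and 83.6% at 0.3, and for level differences 31.3% at 0.1 and 92.5% at 0.3. For rhythm differences, 16.4% were recovered at 1.2-fold and 80.6% at 1.5-fold. False calls made up 3.61% for trend, 7.80% for slope differences, 7.45% for level differences and 2.29% for rhythm differences. In 200 simulated Hes7 curves the mean period was 135.1 min for a true 135 min, and the interval held it in 97.0%. Alternatives were another scaling and DESeq2 1.42.0, limma-voom, other filters, other periods and trends, each experiment alone and each library left out. For each count of genes, 100 orders of the times or splits of the libraries were compared, raised from 50 after the counts at 50 had been seen. Added after the data were seen were permutations of the residuals of the full model, scaled by their leverage and added to the fit without the tested term (limma-trend on log2 CPM, raised from 100 to 1000 after the counts at 100 had been seen), an offset that removes each library's trend with GC content and transcript length, counts thinned to the depth of the shallowest library, and leaving out time points 1 and 16 of Ex4 together.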

Results

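The transcriptome of mouse presomitic mesoderm (PSM) made in culture was followed over nearly 2 cycles of the segmentation clock, the oscillator that times the formation of somites in the embryo. The cells came from epiblast stem cells, pluripotent cells derived from the postimplantation embryo, that carry a luciferase reporter of Hes7, a transcriptional repressor at the core of this oscillator. They were turned into PSM with the GSK3 inhibitor CHIR99021, bFGF, the TGF-β receptor inhibitor SB431542 and the BMP receptor inhibitor LDN193189. In each of 2 independent time courses, named Ex4 and Ex5, 16 dishes were frozen at successive times, and 1 RNA-seq library was made per dish. Ex4 ran from 155 to 405 min and Ex5 from 165 to 425 min. Counts assigned to genes were 19.3 to 29.5 M per library in Ex4 (median 24.1 M) and 16.1 to 28.6 M in Ex5 (median 22.2 M). Of 21886 genes in the table, 11772 passed the expression filter and were tested. The stated purpose of the series was to find the genes that cycle with the Hes7 reporter.

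Hes7 itself rose and fell in both experiments. Its transcript (chromosome 11, 69120404 to 69124055 on the plus strand in mm10, ENSMUSG00000023781.2) ranged from 123 to 284 CPM (counts scaled to library size) in Ex4 and from 152 to 437 CPM in Ex5. The period fitted to both experiments together was 135 min (95% interval 129 to 141 min), with fitted peaks at 212 and 347 min in Ex4 and at 237 and 372 min in Ex5. The fitted peak was 1.93 times the trough in Ex4 and 2.1 times in Ex5, against a residual SD of 0.16 on the log2 scale. The cycle took up 87.7% of the variation that remained after level and linear trend. No permutation of the times within each experiment gave as good a fit (p = 1e-04, the smallest they can give). Fitted alone, Ex4 gave 129 min (122 to 137 min) and Ex5 gave 140 min (130 to 150 min), and the test for separate periods did not pass the threshold (F test, p = 0.0912). The mean of 5 other Notch genes gave 142 min. The luciferase transcript of the reporter, listed as its own row, cycled 1.70-fold with its peak at -1.26 ± 1.81 min (SE) relative to Hes7, where a negative value means an earlier peak.

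**Figure D1:**
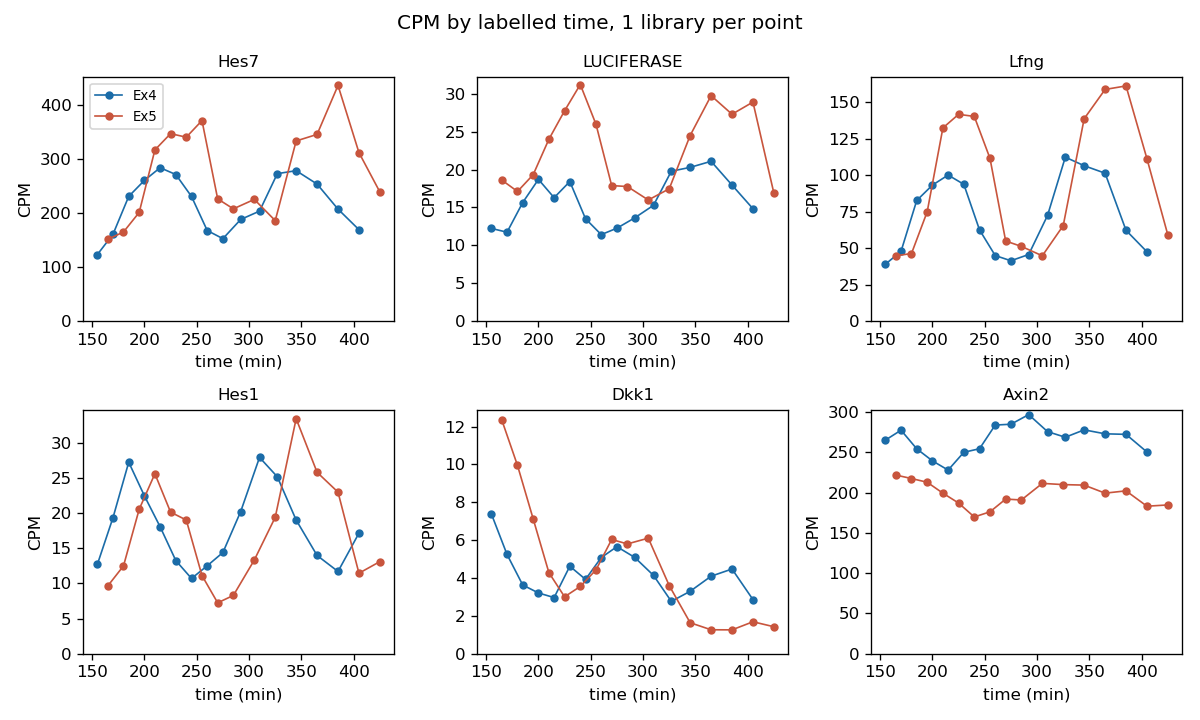
CPM (y axes, from 0) against the labelled time in minutes (x axes) for Hes7, the luciferase reporter transcript, Lfng, Hes1, Dkk1 and Axin2, with 1 point per library (16 in Ex4, 16 in Ex5). Lfng ran from 39.0 to 112 CPM in Ex4 and from 44.8 to 161 CPM in Ex5 in step with Hes7, and Hes1 peaked earlier. Dkk1 was low when Hes7 was high. It was also low in the last library of Ex4 (2.86 CPM, Hes7 170 CPM) and of Ex5 (1.42 CPM, Hes7 239 CPM).

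The next comparison asked which genes cycle with Hes7. Lfng, a glycosyltransferase that modifies Notch receptors, had the largest amplitude, 3.15-fold from trough to peak (log2 1.65 ± 0.08 SE, 32 libraries, adjusted p = 5.37e-18), and peaked at -5.05 ± 0.98 min relative to Hes7. The repressors Hes1 (2.75-fold, log2 1.46 ± 0.09) and Hes5 (2.20-fold), both Notch targets, peaked earlier, at -25.8 ± 1.40 and -25.8 ± 2.16 min. Per1, known as a circadian clock gene, cycled 1.93-fold at -4.41 ± 1.26 min. Dusp4, a phosphatase that acts on ERK and related kinases, cycled 1.76-fold (241 CPM on average) at -8.16 ± 1.15 min, and Efna1, an ephrin ligand, 1.72-fold at -10.9 ± 1.17 min. Dkk1, a secreted Wnt inhibitor of low abundance (4.44 CPM), cycled 2.13-fold (log2 1.09 ± 0.13, adjusted p = 7.15e-07) in nearly opposite phase, at 58.2 ± 2.46 min.

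In all, 155 of the 11772 tested genes passed the rhythm test (edgeR quasi-likelihood F test, adjusted p under 0.05), and 20 of them had a peak-to-trough fold of at least 1.5. The rest were of small amplitude. The median fold over the 155 genes was 1.2, 80 genes lay under 1.2 and 5 at 2 or above. Peaks fell in the part of the cycle centred on the Hes7 peak for 114 genes and in the opposite part for 41. Besides the genes above, the 20 genes of largest amplitude at a mean of at least 5 CPM held the transcription factors Lhx1 (1.85-fold), Junb (1.70-fold), Egr1 (1.47-fold), Irx3 (1.46-fold) and Klf16 (1.44-fold). They also held the ephrin receptor Epha2 (1.60-fold), Shisa3 (1.47-fold), Rnf39 (1.44-fold), Gse1 (1.43-fold), the Notch feedback inhibitor Nrarp (1.42-fold) and the HLH protein gene Id2 (1.41-fold). Dennd2c (1.43-fold) was alone among these 20 in peaking opposite to Hes7, at -64.0 ± 2.68 min. Egr1 lost its call when the Ex5 library of time point 8 or that of time point 9 was left out (adjusted p = 0.0665 and 0.0598) and with a period of 120 min (adjusted p = 0.178). Dennd2c and Shisa3 lost theirs with no time trend in the model (adjusted p = 0.0517 and 0.0586) and with a period of 180 min (0.586 and 0.566). Klf16 (0.395), Rnf39 (0.385) and Gse1 (0.0544) lost theirs at 180 min. With a period of their own, Egr1 (189 min, 95% interval 174 to 209 min), Epha2 (154 min, 148 to 161 min) and Hes5 (150 min, 142 to 158 min) lay above the Hes7 value. Id2 (125 min, 120 to 132 min), Shisa3 (122 min, 113 to 133 min) and Dennd2c (118 min, 112 to 125 min) lay below it. The intervals of 13 of the 19 genes examined held the Hes7 period, and their median was 135 min, but all had been selected with the period fixed at that value. The record spans 1.85 cycles in Ex4 and 1.93 in Ex5, and the calls depended on the model of time: with no trend 62 genes passed, with quadratic time 192, of which 141 were among the 155, and with a period fixed at 180 min 157, of which 42 were among the 155.

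**Figure D2:**
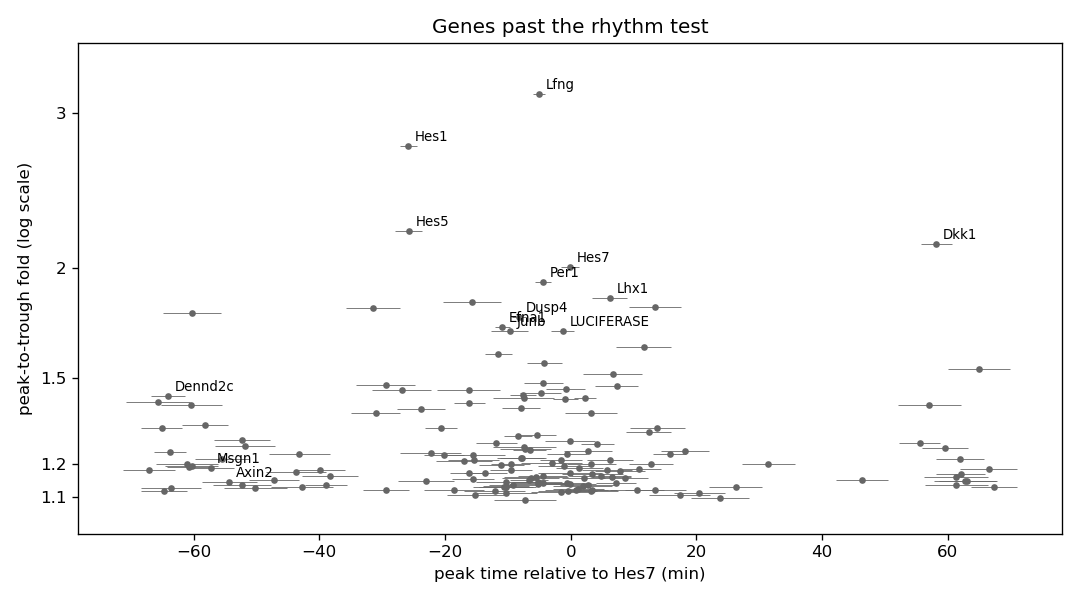
Peak-to-trough fold (y axis, log scale) against the fitted peak time relative to Hes7 in minutes (x axis) for each of the 155 genes past the rhythm test, with horizontal bars of 1 SE. Most points lie near 0 min at small folds, a second group lies near the ends of the axis, opposite to Hes7, and Lfng, Hes1, Hes5 and Dkk1 stand highest.

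Grouped by lists fixed beforehand, the Notch pathway and Hes/Hey list, which also holds Efna1, Id1 and Id2, had the largest share of cycling members. Differences between lists were not tested. Targets of Notch, FGF and Wnt are known to cycle in the embryo, so the tests of these lists partly ask whether known cyclers cycle here. They do not show that a pathway as such cycles most. Of 20 measured members of the Notch list 12 passed the test, where 0.263 would be reached at the rate of all genes (two-sided Fisher exact test, adjusted p = 4.06e-17), and 13 passed when adjusted over the list alone. They included Lfng, Hes1, Hes5, Nrarp and Efna1, as well as Hey1 (1.25-fold), Notch1 (1.19-fold) and the ligand Dll1 (1.17-fold at 853 CPM). With no time trend in the model the calls of Hey1 (adjusted p = 0.345), Notch1 (0.292), Dll1 (0.0776) and Id1 (0.0871) were lost at nearly the same amplitude (log2 0.28, 0.28, 0.20 and 0.32, against 0.32, 0.26, 0.23 and 0.30). Those of Id2 (0.389) and Maml3 (0.851) were lost at a smaller one (log2 0.32 and 0.06, against 0.49 and 0.22). Here and below, amplitudes under an alternative are taken along the phase of the main fit, so a smaller one can also come from a shifted phase. Id1 also lost its call without any 1 of 11 libraries (up to 0.0815), and Hey1 when counts were thinned to equal depth (0.122). At a period of 180 min calls were lost for Hes7 (adjusted p = 0.0801), Efna1 (0.130), Nrarp (0.0995), Id2 (0.449), Dll1 (0.570), Hey1 (0.0843), Notch1 (0.220) and Id1 (0.837). At 150 min Id1 (0.310) lost its call, and at 120 min Maml3 (0.206) and Hey1 (0.0682) lost theirs. Hes7 is one of the 12 and, as the source of the phase, no independent test. The other members, such as Dll3 (1.07-fold, adjusted p = 0.426) and Jag1 (1.06-fold, adjusted p = 0.745), did not pass. Of 23 FGF/ERK targets and feedback genes 6 passed (adjusted p = 3.97e-06; 14 when adjusted over the list alone). These were Dusp4, Egr1, Snai1 (1.27-fold), Fgf4 (1.19-fold), Dusp6 (1.15-fold) and Spry2 (1.12-fold), while Fgf8 (1.05-fold, adjusted p = 0.682) and Etv4 (1.02-fold, adjusted p = 0.797) did not. Dusp6 lost its call without the Ex5 library of time point 9 (adjusted p = 0.0505). With no time trend Fgf4 (adjusted p = 0.0740), Spry2 (0.0637) and Dusp6 (0.250) lost theirs, at log2 amplitudes of 0.32, 0.15 and 0.16 against 0.25, 0.16 and 0.20, and at 180 min Dusp4 did (0.101, log2 0.48 against 0.82). Of 23 Wnt targets and feedback genes 5 passed (adjusted p = 5.15e-05; 12 when adjusted over the list alone). Besides Dkk1 these were Sp8 (1.19-fold), Apcdd1 (1.18-fold), Axin2 (log2 0.19 ± 0.04 at 232 CPM) and Tnfrsf19 (log2 0.18 ± 0.03), while Lef1 (1.04-fold, adjusted p = 0.536) did not. With no time trend in the model the calls of Dkk1 (adjusted p = 0.0871) and Axin2 (0.0652) were lost at nearly the same amplitude (log2 1.09 and 0.18), and those of Apcdd1 (0.770) and Tnfrsf19 (0.863) at a smaller one (log2 0.08 and 0.05). At a period of 120 min those of Sp8 (0.115), Axin2 (0.190) and Apcdd1 (0.0621) were lost, and at 180 min those of Tnfrsf19 (0.103, log2 0.12) and Apcdd1 (0.0966, log2 0.17).

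Cycling genes were found in further lists. Of 16 measured PSM genes 5 passed (adjusted p = 9.61e-06; 9 when adjusted over the list alone): Hes7 and Dll1, which are also in the Notch list, Cdx2 (1.15-fold), Cyp26a1 (1.21-fold) and Msgn1 (1.19-fold), a PSM transcription factor that peaked at -57.3 ± 3.78 min. With no time trend Dll1, Cyp26a1 (adjusted p = 0.119) and Msgn1 (0.119) lost their calls, the latter 2 at log2 amplitudes of 0.26 and 0.32 against 0.28 and 0.25. Msgn1 lost its call at 120 min (0.105, log2 0.18) and Dll1 (0.570, log2 0.04), Cdx2 (0.127, log2 0.14) and Cyp26a1 (0.0686, log2 0.22) at 180 min. Of 8 BMP targets 3 passed (adjusted p = 0.000478; 3 when adjusted over the list alone), Id3 (1.38-fold; lost at 180 min, adjusted p = 0.308), Msx1 (1.37-fold; lost at 120 min, 0.133) and Smad7 (1.45-fold at 2.1 CPM). Smad7 lost its call without any 1 of 21 libraries (adjusted p up to 0.144), with no trend (0.404), at 150 and 180 min (0.167 and 0.544), with the GC correction (0.0672), with thinning (0.152) and without Ex4 time points 1 and 16 (0.0753). Of 12 immediate early genes 3 passed (adjusted p = 0.00150; 5 when adjusted over the list alone), Junb, Ier2 (1.17-fold), both lost at 180 min (adjusted p = 0.0992 and 0.293), and Nr4a1 (log2 0.27 ± 0.06), which lost its call without any 1 of 12 libraries (adjusted p up to 0.0959), with no trend (0.126), at 120 and 180 min (0.124 and 0.180), with the GC correction (0.0676), with thinning (0.0765) and without Ex4 time points 1 and 16 (0.137). Of 12 circadian clock genes 2 passed (adjusted p = 0.0298; 2 when adjusted over the list alone), Per1 and Dbp (1.24-fold). Dbp (log2 0.31 ± 0.06) lost its call with no trend (adjusted p = 0.124) and with thinning (0.0616) at about the same amplitude (log2 0.36 and 0.28), and at 180 min (0.523) at a smaller one (log2 0.15). The list call rests on these 2 genes. A single member passed of 10 anterior PSM and somite genes (Fst, 1.28-fold; lost without the Ex5 library of time point 7, adjusted p = 0.0758), of 8 neural genes (Irx3), of 5 lateral, intermediate and vascular mesoderm genes (Lhx1), of 15 stress genes (Ddit4, lost without any 1 of 12 libraries, adjusted p up to 0.0860), of 9 retinoic acid genes (Cyp26a1) and of 6 YAP targets (Ajuba). Calls were also lost with no trend for Fst (adjusted p = 0.239, log2 0.90 against 0.35), Ddit4 (0.158, log2 0.16 in both), Irx3 (0.243, log2 0.58 against 0.54) and Lhx1 (0.204, log2 0.69 against 0.89). At 180 min they were lost for Fst (0.416), Irx3 (0.747) and Ajuba (0.703), at 150 min for Fst (0.206) and Ajuba (0.0798), and at 120 min for Ddit4 (0.155). Ddit4 also lost its call with the GC correction (0.115), with thinning (0.0587) and without Ex4 time points 1 and 16 (0.0734). The Fisher tests of these 6 lists did not pass (adjusted p from 0.160 to 0.278), and 4, 2, 2, 1, 1 and 2 members passed when adjusted over the list alone. None passed of 26 Hox genes, 18 G1/S genes, 18 G2/M genes, 16 glycolysis genes, 14 cholesterol synthesis genes, 6 pluripotency genes and 2 endoderm genes. Adjusted over the list alone, 1 Hox gene, 1 glycolysis gene and 1 pluripotency gene passed, and 0 in the other 4 lists.

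The phases of the Notch, FGF and Wnt lists were compared because targets of these pathways are known to cycle at different phases in the embryo. The circular mean of the 12 cycling Notch genes lay at -13.8 min relative to Hes7 (circular SD 11.7 min), that of the 6 FGF genes at -25.2 min (SD 17.0 min) and that of the 5 Wnt genes at -53.6 min (SD 14.3 min). Axin2 at -54.4 ± 4.39 min, Sp8 at -60.3 ± 4.19 min and Dkk1 at 58.2 ± 2.46 min peaked nearly opposite to Hes7. Tnfrsf19 at -38.9 ± 3.36 min and Apcdd1 at -39.9 ± 4.02 min peaked nearer to it. Wnt and Notch genes differed by -39.8 min (exact permutation test over 6188 labelings of genes, adjusted p = 0.000323), and at a period of 180 min this call was lost (-37.6 min, p = 0.186). FGF and Notch genes differed by -11.3 min, which did not pass (exact permutation test over 18564 labelings, adjusted p = 0.112), and the difference shrank to -1.44 min with quadratic time. Genes are not independent replicates, so the mean standardised curve of the cycling members of each list was also fitted per experiment. These members had been chosen on the same libraries, so the likeness of the experiments is no independent check. The Wnt curve peaked at -57.0 ± 4.73 min in Ex4 and -53.9 ± 3.20 min in Ex5, the Notch curve at -14.6 ± 1.66 and -13.6 ± 2.02 min, and the FGF curve at -24.4 ± 2.63 and -19.6 ± 4.31 min.

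Each experiment was then analysed on its own. In Ex4 alone 40 genes passed the rhythm test and in Ex5 alone 52, and 20 genes passed in both, where 0.177 would overlap by chance (two-sided Fisher exact test, p = 1.56e-38). These counts were 18, 13 and 10 with no time trend, and 57, 117 and 39 with quadratic time. Both fits took their clock from the joint Hes7 fit, and genes are not independent. The Fisher p-value therefore does not measure agreement between repeated experiments. Lfng cycled 2.78-fold in Ex4 and 3.55-fold in Ex5, Hes1 2.33-fold and 3.29-fold, and Per1 1.79-fold and 2.07-fold. Peak times relative to Hes7 of the 20 shared genes differed between the experiments by a median of 2.84 min and at most 11.7 min. Over the 155 genes of the joint fit the median difference was 5.89 min, and 154 of them lay within 1/6 of a cycle, but these genes had been selected on the joint fit. No gene differed in rhythm between the experiments (edgeR interaction test, 0 genes), with 644 genes at an unadjusted p under 0.05. DESeq2 and limma-voom also gave 0 genes. With no filter 2 genes differed, at 180 min 3, with spline time 1 and with one phase origin for both experiments 25. In simulated counts, a rhythm present in Ex5 alone was found in 16.4% of genes at 1.2-fold and in 80.6% at 1.5-fold. Differences in weak rhythms would therefore mostly be missed, and the count of 0 does not show that the rhythms are the same.

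Over the sampled hours the cells lost epiblast transcripts. Cdh1, the epithelial cadherin, changed by -0.59 ± 0.02 log2 per 100 min (adjusted p = 7.82e-23), and Pou5f1, the pluripotency factor Oct4, by -0.54 ± 0.02. Fst, which encodes the activin antagonist follistatin, fell most among genes at 5 CPM or more, by -0.80 ± 0.04, and the metallothionein Mt2 fell by -0.59 ± 0.05. Among rising genes, Sost, a secreted Wnt inhibitor, gained 0.71 ± 0.06 log2 per 100 min, Cstf3 0.71 ± 0.03, the lactate transporter Slc16a3 0.68 ± 0.06, Tenm4 0.56 ± 0.03 and Bnip3 0.56 ± 0.05. The other rising genes of the top 10 were Ovgp1, Loxl2, Ddx58, Ism1 and Ptprz1 (slopes 0.69, 0.58, 0.58, 0.56 and 0.55), and the other falling ones were Slc46a3, Dlgap3, Nefm, Srxn1, Ttyh1, Hap1 and Pid1 (slopes -0.70, -0.66, -0.64, -0.57, -0.56, -0.56 and -0.55). Altogether 6280 genes had a linear trend past the test, 3153 rising and 3127 falling, with a median size of 0.10 log2 per 100 min; 107 reached 0.5. In Ex4 alone 3747 genes passed and in Ex5 alone 5531, and 2389 of the 2485 genes past the test in both moved the same way.

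**Figure D3:**
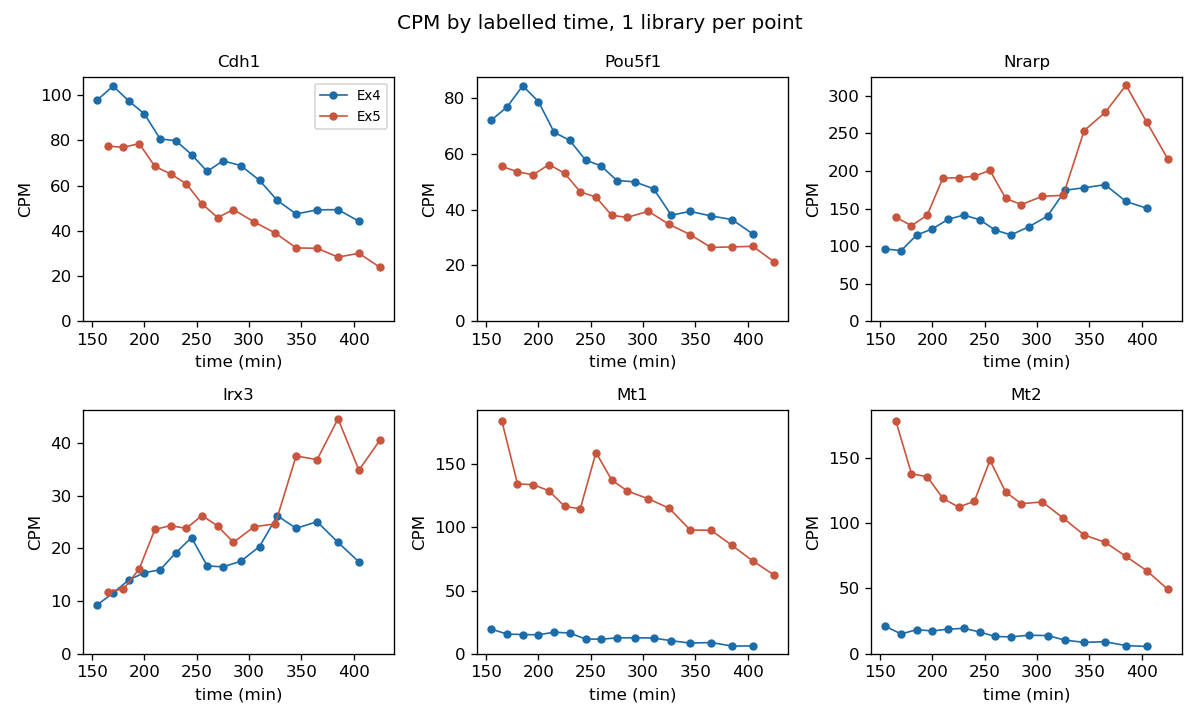
CPM (y axes, from 0) against the labelled time in minutes (x axes) for Cdh1, Pou5f1, Nrarp, Irx3, Mt1 and Mt2, with 1 point per library. Cdh1 and Pou5f1 fell and Nrarp and Irx3 rose in both experiments, and Mt1 and Mt2 lay far higher in Ex5 than in Ex4 at all times.

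By list, 13 of 20 Notch genes rose and 1 fell, among them Nrarp (0.32 ± 0.02 log2 per 100 min), Notch1 (0.26 ± 0.02) and Hey1 (0.29 ± 0.03); camera with a preset correlation gave an adjusted p = 0.000716, and the call was lost with an estimated correlation (adjusted p = 0.436). Of 6 pluripotency and epiblast genes 5 fell and 1 rose, with Pou5f1, Cdh1, Epcam (-0.31 ± 0.02) and Sox2 (-0.22 ± 0.03) among those that fell, and this list held under both settings (adjusted p = 0.000161 preset and 0.0451 with an estimated correlation). Of 16 glycolysis genes 12 rose and 2 fell, with Ldha (0.14 ± 0.02) and Tpi1 (0.15 ± 0.02) among the rising ones and the glucose transporters Slc2a1 (-0.18 ± 0.02) and Slc2a3 (-0.16 ± 0.02) the falling ones; the adjusted p = 0.0128 at the preset correlation became adjusted p = 0.731 with an estimated correlation. Of 16 PSM genes 5 rose and 8 fell: Tbx6 (0.18 ± 0.02) and Dll3 (0.17 ± 0.02) rose, and Wnt3a (-0.25 ± 0.02) and Cdx1 (-1.24 ± 0.06 at 3.18 CPM) fell. Of 26 Hox genes 13 rose, such as Hoxd3 (0.37 ± 0.03), Hoxb3 (0.22 ± 0.02) and Hoxc6 (0.19 ± 0.02), and 9 fell. Of 10 anterior PSM and somite genes 4 rose, including Foxc1 (0.23 ± 0.03) and Foxc2 (0.49 ± 0.05), and 4 fell. Of 23 FGF genes 6 rose and 8 fell, including Fgf4 (-0.20 ± 0.02), Dusp2 (-0.51 ± 0.05) and Dusp4 (-0.16 ± 0.02), and of 23 Wnt genes 8 rose, including Nkd2 (0.37 ± 0.02) and Tnfrsf19 (0.17 ± 0.01), and 8 fell. Rising and falling members numbered 4 and 8 of 18 in G1/S, 6 and 2 of 18 in G2/M, 5 and 3 of 12 in the circadian list, 2 and 1 of 12 in the immediate early list (Ier3 lost its call without any 1 of 17 libraries, adjusted p up to 0.222, and Nr4a1 without Ex4 time point 1 or Ex5 time point 16, up to 0.0637), and 2 and 8 of 15 in the stress list. They numbered 3 and 2 of 8 BMP targets, 1 and 2 of 9 retinoic acid genes, 3 and 2 of 6 YAP targets, 7 and 2 of 14 cholesterol synthesis genes, 3 and 3 of 8 neural genes, 0 and 3 of 5 lateral, intermediate and vascular mesoderm genes, and 1 and 1 of 2 endoderm genes. None of these other lists passed camera (adjusted p from 0.243 to 0.933), and for the FGF list the median slope (0.01) and the mean (-0.04) differ in sign, as they do for the neural list (median -0.07, mean 0.01). The first and last Ex4 libraries, whose values followed GC content and transcript length more than the others (SD 0.101 and 0.106 log2 across genes, against 0.0118 to 0.0683 in the other 30), stand at the ends of this time axis. Without them 6193 genes had a trend.

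Levels differed widely between the experiments. At 285 min, the metallothionein genes Mt1 and Mt2, neighbours on chromosome 8, were 3.35 ± 0.07 and 3.11 ± 0.07 log2 higher in Ex5 (adjusted p = 2.01e-32 and 1.70e-30), with mean levels of 12.4 CPM (SD 3.87, n = 16) against 118 CPM (SD 30.8, n = 16) for Mt1. The glycolytic enzyme Pfkp (1.66 ± 0.06), Slc16a3 (1.59 ± 0.09) and Adssl1 (1.45 ± 0.05) were also higher in Ex5. Lower in Ex5 were the ephrin receptor Epha5 (-1.64 ± 0.05), Ano3 (-1.54 ± 0.07), the homeobox genes Msx1 (-1.54 ± 0.06) and Hoxa7 (-1.54 ± 0.03), and Perp (-1.50 ± 0.05). In total 6485 genes differed, 3227 higher and 3258 lower in Ex5, with a median size of 0.16 log2; 105 differed by at least 1 log2. The experiments are 1 culture series each, so p-values here measure the spread between dishes and not between repeated experiments. With the 4 shared minutes alone 2881 genes differed. The zero of the labelled time is not given, so levels at 285 min and at shared minutes assume that it is common to both experiments. The share of mitochondrial counts also differed, with a median of 0.406% in Ex4 and 0.299% in Ex5, and was highest in Ex4 time point 16 (0.682%, against at most 0.558% in the other libraries).

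By list, 12 of 14 cholesterol synthesis genes were higher in Ex5 and 0 lower (camera, adjusted p = 7.38e-09 at the preset correlation and 0.0249 with an estimated correlation). Of 16 glycolysis genes 12 were higher and 3 lower (adjusted p = 2.06e-05; adjusted p = 0.199 with an estimated correlation), with Ldha 0.43 ± 0.02 higher and Slc2a1 -0.56 ± 0.03. Of 20 Notch genes 13 were higher and 3 lower (adjusted p = 0.0115; 0.271 with an estimated correlation), with Nrarp 0.48 ± 0.03 higher. Of 12 immediate early genes 8 were higher and 0 lower (adjusted p = 0.0170; 0.204 with an estimated correlation). Of 6 pluripotency genes 1 was higher and 4 lower (adjusted p = 0.0115; 0.199 with an estimated correlation), including Sox2 (-1.16 ± 0.04), which is also in the neural list, where 1 was higher and 5 lower of 8 (adjusted p = 0.00817; 0.199 with an estimated correlation). Of 18 G2/M genes 1 was higher and 9 lower (adjusted p = 0.0459; 0.439 with an estimated correlation). The remaining lists did not pass (adjusted p from 0.0888 to 0.839). Their higher and lower members numbered 11 and 9 for FGF, 6 and 12 for Wnt, 8 and 8 for PSM, 3 and 5 for anterior PSM and somite, 9 and 7 for Hox, 5 and 3 for G1/S, 5 and 3 for circadian, 9 and 4 for stress, 4 and 2 for BMP, 5 and 2 for retinoic acid, 1 and 4 for YAP, 1 and 3 for lateral, intermediate and vascular mesoderm, and 0 and 0 for endoderm. Median and mean differ in sign for the Hox list (0.05 and -0.13), the BMP list (0.05 and -0.20) and the PSM list (0.02 and -0.02).

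Slopes also differed between the experiments. The smallest p-values belonged to Cpne1, which rose faster in Ex5 (slope difference 0.33 ± 0.03 log2 per 100 min, adjusted p = 5.49e-09), and to Rai14 (-0.27 ± 0.03), Utp14b (-0.34 ± 0.03), the cysteinyl-tRNA synthetase gene Cars (-0.26 ± 0.03) and the amino acid transporter Slc7a5 (-0.25 ± 0.03). Cars went from a slope of -0.01 in Ex4 to -0.28 in Ex5, and Slc7a5 from 0.02 to -0.25. Altogether 1894 genes differed in slope, 827 with a higher and 1067 with a lower slope in Ex5, with a median size of 0.14 log2 per 100 min. Across genes the slopes of the experiments, each fitted alone, correlated at r = 0.712, and genes are not independent replicates. Without the first and last Ex4 libraries 1338 genes differed, 528 of them with a higher slope in Ex5.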

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

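The tests of the form of the time trend and of the amplitude with no trend, the permutations of residuals and the look at single splits and orders were chosen after the result was seen. The difference in slope between the experiments covers 1894 genes by the interaction test. In 100 splits of the libraries into 2 sets of 16, the real one included, only the real split (1 of 100) gave as many, and the highest of the others gave 3. These splits leave the level differences and trends in the spread and so hold the other counts near 0, which excludes nothing. The residuals of the full model were therefore permuted over the libraries and added to the fit without the tested term (limma-trend, 1000 permutations for each count, the real order included). There 1918 genes differed in slope in the real order, reached by it alone (1 of 1000), with 411 as the highest of the others. This argues against a random order of the residuals as the source. The permutations mix the experiments and do not keep the order in time, so drift shared by neighbouring libraries of 1 culture is not excluded. Of the 1894 genes, 71.1% stayed called after the trend of each library with GC content and length was removed, and 79.8% after thinning to equal depth, which argues against either as the whole source. Without the libraries of Ex4 time points 1 and 16, 63.9% stayed called, short of the share set beforehand for excluding those libraries as the source, so their part remains open and the rest may reflect different courses of the cultures, which the design cannot separate from other differences between them.

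Among the genes named above, the slope in Ex5 exceeded that in Ex4 by 0.56 log2 per 100 min for Sost, 0.28 for Cstf3, 0.43 for Ovgp1, 0.33 for Cpne1, 0.37 for Foxc2 and 0.19 for Nkd2. The difference was -0.60 for Slc46a3, -0.58 for Dlgap3, -0.49 for Nefm, -0.17 for Cdh1, -0.35 for Srxn1, -0.43 for Ttyh1, -0.40 for Hap1 and -0.33 for Pid1. It was -0.27 for Rai14, -0.34 for Utp14b, -0.26 for Cars, -0.25 for Slc7a5, -0.22 for Wnt3a, -0.17 for Slc2a3, -0.38 for Dusp2, -0.19 for Dusp4 and -0.13 for Tnfrsf19. Each was past the interaction test.

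The rhythm calls under 1.2-fold number 80. With the GC content and length trend removed 88.8% of them stayed called, which argues against that bias as the whole source. With quadratic time 87.5% stayed called and with spline time 71.2%, but with no time trend 26.2%. With no trend the median ratio of their amplitude, taken along the phase of the linear fit, to that with linear time was 0.996 (quartiles 0.889 and 1.08). That of the standard error was 1.31, so the lost calls came mostly with a larger error and not a smaller amplitude. This argues against an amplitude made by the linear trend for the set. Of the 59 genes that lost the call, 44 kept at least 0.8 of the amplitude and 5 fell under 0.5, and for such genes the part of the form of the time trend remains open. In 100 orders of the times within each experiment, the real one included, only the real order (1 of 100) gave as many rhythmic genes as 155 or as many as 20 above 1.5-fold, and the highest of the others gave 1 for both. Those orders leave the trends in the spread and hold the counts near 0, so they exclude nothing. With permuted residuals, 148 rhythmic genes in the real order were reached in 9 of 1000. The period and phase stayed those fitted to Hes7 in the real order, which favours the real count, so chance is not excluded. The highest of the others gave 709 and 32 of the others gave any. A large count of weak rhythms can thus arise by chance when libraries vary together. Of the first 100 permutations 3 reached 148 genes, and the number of permutations was raised because of that. The 22 genes above 1.5-fold were reached by the real order alone (1 of 1000, highest of the others 10), with the same fixed clock. These permutations do not keep the order of the libraries in time. They cannot tell a rhythm at the Hes7 period from another smooth course over the short record. With the period fixed at 120, 150 and 180 min, 138, 145 and 157 genes passed, of which 103, 115 and 42 were among the 155.

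For the 6280 trend genes only the real order (1 of 100) gave as many, and with permuted residuals only the real order (1 of 1000, 6265 genes, highest of the others 759). This argues against a random order of the residuals as the source, but not against drift shared by neighbouring libraries of 1 culture. In the orders of the times the highest of the others gave 730 genes. Its times had the largest absolute correlation with the real times of the 99 other orders (r = -0.564), but an order at r = -0.510 gave 0 genes and 1 at r = -0.249 gave 173, so this correlation alone does not account for the counts. The 6485 level differences were reached by 1 of 100 splits, with 7 genes as the highest of the others. Those splits leave the difference in the spread. With permuted residuals 6472 genes were reached by the real order alone (1 of 1000, highest of the others 2333), which argues against a random order of the residuals here as well. For rhythm differences all 100 of 100 splits gave at least the observed 0 (edgeR, 644 at an unadjusted p under 0.05, DESeq2 0, limma-voom 0), as did 1000 of 1000 permutations of residuals. With 0 observed this holds by definition and carries no information. A single other split gave any, 1881 genes. It was the split whose interaction terms overlapped most with the real experiments: they took up 38.0% of the difference between Ex4 and Ex5, against a median of 6.73% over the 99 other splits. The level differences between the experiments may be behind this count, but 27 of the other permutations of residuals also gave some genes, up to 1053, so a large count in 1 draw need not have such a source.

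Mt1 and Mt2 stood apart in the level comparison. After the GC content and length correction their mean difference was 3.19 log2, which argues against that bias. Slc30a1, a zinc exporter induced by zinc, was -0.22 ± 0.07 log2 in Ex5 relative to Ex4 (upper 95% bound -0.07), which argues against more zinc in Ex5. The idea of lower oxygen came from seeing Slc16a3, Pfkp and glycolysis genes higher in Ex5. Over 19 tested genes of a list of oxygen-responsive genes that leaves these out, the median difference was 0.32 log2, 15 were higher and 0 lower in Ex5 (camera with an estimated correlation, p = 0.0116), with Ak4 at 0.84 ± 0.05 and Egln3 at 0.59 ± 0.04. Slc2a1 (-0.56 ± 0.03) and Slc2a3 (-0.51 ± 0.03), glucose transporters known to rise at low oxygen and not in that list, were lower in Ex5, which goes against the idea. Over the sampled hours Mt1 and Mt2 fell in Ex5, from 184 to 62.4 CPM and from 179 to 49.2 CPM, while Slc16a3, Bnip3 and Ldha rose, which also goes against it. The median shift of the oxygen list is far smaller than the difference of Mt1 and Mt2. Lower oxygen in Ex5 may contribute, as a hypothesis that leaves these observations unexplained. Oxygen was not measured, and other differences between the cultures stay open.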

How the results depend on the processing

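The GC content and length correction, the thinning and the joint removal of Ex4 time points 1 and 16 were chosen after seeing the data. Rhythmic genes numbered 68 with one phase origin for both experiments, 62 with no time trend, 40 in Ex4 alone and 52 in Ex5 alone, against 155, and stayed within 1.5 times elsewhere (124 to 229 without 1 library each). Those above 1.5-fold numbered 11 at the filter of 5 CPM and 13 in Ex4 alone, against 20 (17 to 21 without 1 library each). The stricter filter removes low genes, and single experiments have fewer libraries; the other causes were not tested. Genes differing in rhythm numbered 2 with no filter, 3 at 180 min, 25 with one origin and 1 with spline time, against 0 (0 to 0 without 1 library each). With one origin the experiments are set out of phase by the lag of 24.8 min between their Hes7 peaks. Trend genes numbered 3747 in Ex4 alone (2002 rising, 1745 falling) and 5939 to 6556 without 1 library each (rising 2975 to 3304, falling 2963 to 3252). Slope differences numbered 1485 to 2025 without 1 library each (higher 570 to 899, lower 883 to 1137), and the higher ones 528 without both Ex4 libraries. Level differences numbered 2881 (1395 higher, 1486 lower) at the 4 shared minutes, where fewer libraries enter, and 6321 to 6563 without 1 library each (higher 3143 to 3276, lower 3169 to 3300).

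The Hes7 period was 129 to 142 min under its alternatives and 133 to 136 min without 1 library each. Genes rhythmic in Ex4 alone, in Ex5 alone and in both numbered 18, 13 and 10 with no time trend, and 117 in Ex5 alone and 39 in both with quadratic time; the cause was not tested. At 180 min the Notch phase was -34.4 min, the FGF minus Notch difference turned to 12.2 min (p = 0.382; -2.12 min at 150 min and -1.44 min with quadratic time) and the Wnt minus Notch difference was -37.6 min (p = 0.186). The FGF phase was -15.5 min with quadratic time and -8.39 min in Ex5 alone, where it rests on Dusp4 alone. With members of at least 1.5-fold the FGF phase was -8.16 min and the Wnt phase 58.2 min, each from 1 gene. By list, 2 anterior PSM and somite genes (adjusted p = 0.0273) and 2 YAP targets (adjusted p = 0.0109) passed with quadratic time and 1 lateral mesoderm gene at 5 CPM (adjusted p = 0.0341), enough for those Fisher tests to pass, and the immediate early list lost its level call at 5 CPM (median 0.10, adjusted p = 0.111).

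Of the 46 named rhythm calls, DESeq2, limma-voom and quadratic time kept 46, no trend lost 24 (among them Lhx1, Irx3, Id2, Dll1, Hey1, Notch1, Fgf4, Dusp6, Msgn1 and the Wnt genes named above except Sp8), 120 min lost 10, 150 min lost 4 and 180 min lost 27. The GC correction lost 3, thinning 5 and the 2 left-out Ex4 libraries 4. Without single libraries, calls were lost for Smad7 (21 libraries), Nr4a1 and Ddit4 (12 each), Id1 (11), Egr1 (2), Dusp6 (1) and Fst (1), and trend calls for Ier3 (17) and Nr4a1 (2). Among the named genes signs turned only for ones below the threshold. At 180 min the amplitude along the reported phase was -0.072 for Heyl, -0.069 for Dact1 and Wnt5a, -0.059 for Has2, -0.046 for Notch2, -0.031 for Spred2, -0.026 for Dll3, -0.011 for Rbpj and Fgfr1, -0.0059 for Notch3 and -0.0030 for Lef1. It was -0.030 for Dact1 with no trend. At 120 min it was -0.00022 for Fgf3, -0.019 for Rspo3 and -0.026 for Sfrp1. With the GC correction it was -0.0080 for Etv4 and -0.018 for Rspo3, and with thinning -0.0023 for Sfrp1. Without 1 library each it ranged from -0.031 to 0.024 for Rspo3 and from -0.0067 to 0.017 for Sfrp1.

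The time point numbers do not pair the libraries: 14 of 16 same-number pairs correlated above 0.1 (0.047 to 0.545), and 2 of 16 correlated best with their own number. After time and phase were removed, 3 pairs correlated above 0.1 and 0 correlated best with their own number. With the number as a block 6052 genes differed in level. Small effects were often missed: in simulated counts 13.4% of slope differences of 0.1 were found.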

Other observations

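The tests of the Hes7 neighbourhood were chosen after the rhythm of Borcs6 and 9130213A22Rik had been seen. Per1, the circadian gene that cycled with Hes7, lies 10.4 kb from it on chromosome 11 (69095217 to 69109960). Borcs6, 58.8 kb away, also cycled (1.29-fold, adjusted p = 9.84e-05), and the unadjusted p was 0.00779 for Vamp2 (log2 0.19 ± 0.06) and 0.0376 for Aurkb (1.06-fold). Ctc1, Tmem107 and Aloxe3 had p of 0.727, 0.0837 and 0.562. 9130213A22Rik, which overlaps Hes7 on the other strand, passed as well (1.83-fold at 1.22 CPM), but its reads may be those of Hes7. Whether the rhythm may span the Hes7 neighbourhood stays open. Among the 5 other tested genes within 100 kb, the smallest unadjusted p was that of Vamp2, and its adjusted p of 0.207 did not pass. Aurkb, which is among these 5, is also in the G2/M list, so its rhythm had been tested there. Rhythmic genes with a rhythmic, not overlapping gene within 100 kb numbered 12 in the whole genome, against a median of 6 in 10000 random gene sets (one-sided p = 0.118), which leaves open whether closeness is general. Without the Hes7 window the number was 8 against 6 (one-sided p = 0.395). Common regulation of the locus was not tested.

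A later point of the same course could have set the level differences between the experiments. Across the 11772 genes, level difference and mean slope correlated at r = 0.065 (Spearman 0.026), and of 3702 genes past both tests 50.9% had the same sign, which argues against this idea as the whole source. Genes are not independent replicates. The main axis of variation between libraries (first principal component, 36.8% of the variance) rose with time in both experiments (r = 0.955 in Ex4, 0.905 in Ex5). It was higher in every Ex5 library than in any of Ex4. The second (23.0%) fell with time and overlapped between the experiments. On it the Ex5 libraries at 165, 180 and 195 min (25.3, 22.3 and 20.4) lay above every Ex4 library (at most 11.0). That is the early side, the reverse of a later point. The Notch, glycolysis and pluripotency lists shifted in level in the direction of their trend. G2/M shifted against it (median slope 0.02, median level difference -0.05), and the neural slopes had no common sign. With an estimated correlation, only the pluripotency trend call of these lists held. Whether a later point accounts for a part stays open.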
